A study of Homo sapiens with 2 samples.

How the data were processed

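RNA-seq was measured in 2 libraries of the human lung cancer line H1299, 1 per group: a control with no treatment and a PHF12 knockdown. Groups were taken from the treatment label of each sample, and the columns of the table were matched to the samples by their titles. Per the labels' protocols, mRNA was enriched with oligo(dT), fragmented, made into libraries with a NEBNext Ultra RNA kit and sequenced as paired-end reads on an Illumina instrument. The knockdown sample's title carries the prefix si, and the control's title ends in nc while its treatment label gives none. The oligonucleotide sequences and whether the control cells received one are not given in the sources used here.

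The table lists 38637 genes with their type, position and length. Per the submitters' processing notes, reads were aligned to hg38 with HISAT2 and counted with HTSeq, and the versions and the strand setting are not given in the sources used here. Per the file headers, the authors deposited raw counts per gene, which are whole numbers with different totals in the 2 columns. The authors also deposited TPM values, and dividing each count by the listed gene length and scaling each column to a sum of 1000000 returned them to within 1e-06. No line of the table lacked a gene name, and each column of counts or TPM used was matched to a sample. The mitochondrial genes listed are 22 tRNA and 2 rRNA genes. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. Values of multigene families and of genes with pseudogenes are uncertain too, and only some of them are marked below. Poly(A) selection limits what non-polyadenylated RNAs and replication-dependent histone genes can show.

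From the deposited counts, trimmed mean of M-values (TMM) factors were computed with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) and were 0.997 for the control and 1.00 for the knockdown library. CPM (counts per 1000000 counts) were computed on the scaled library sizes. Genes with a mean of at least 1 CPM over both libraries were kept, 14559 in all. The log2 fold change was that of the knockdown CPM plus 0.5 over the control CPM plus 0.5, which pulls the folds of genes with few counts towards 0. Folds and log2 ratios printed for the study genes and for the genes named by size carry no pseudocount. The same holds for every interval of a gene, which is the exact conditional Clopper-Pearson 95% interval for the ratio of 2 Poisson counts. The counting interval of a list median is the central 95% of its medians over 200 Poisson redraws of the counts, with the pseudocount of 0.5 kept. An interval above 0 was found for 2952 genes and below 0 for 3038, but reads of 2 libraries compare those libraries and not the conditions. With 1 library per group no p-value was made and genes were counted by a rule of size, at least 2-fold. Further computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

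The groups, the rule of size, the rule for named genes, 49 gene lists and the other settings listed below as chosen in advance were set before the data were examined. Genes named are PHF12, HDAC1, EGFR, AKT1, AKT2, ACTB and GAPDH. Also named are the 12 highest and 12 lowest protein-coding genes by log2 fold change with a mean of at least 5 CPM and a counting interval that excludes no difference, and for each list the members with the largest absolute log2 fold change; some genes and 1 list that these rules select are not reported here. A list with at least 5 genes past the filter was described by its median, with the percentile of the median among 10000 random lists of the same size matched on mean expression in 20 bins. Lists of other cell types and of RNA quality were included.

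The settings chosen in advance as alternatives were scaling by total counts, DESeq2 1.42.0 size factors, pseudocounts of 0.1 and 1, the deposited TPM values in place of counts, no expression filter, a minimum of 5 CPM, protein-coding genes only, a fold of at least 1.5, and the knockdown library thinned to 24739820 counts. The alternatives added after the data were seen were removal of a cubic trend of the log2 fold change on GC content and transcript length, for the 97.6% of protein-coding genes with a GENCODE release 29 transcript, and leaving out genes that hold an over-represented word.

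The search for words used the longest annotated 3′ UTR per gene in GENCODE release 29, at least 20 bases long, and was chosen after the fold changes were seen. A 3′ UTR was found for 97.2% of the protein-coding genes measured. Each word of 7 bases was counted as present or absent in the genes at least 1.5-fold lower or higher. Its expected number was taken from genes in the same of 20 bins of 3′ UTR length, and 1000 random gene sets matched on expression and 3′ UTR length gave the range of the top word by chance.

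The rule of size and the intervals were tested on simulated counts. These were drawn for the 38637 genes from the means and sizes of the real libraries and scaled by total counts, not by TMM. With no true difference, 0 genes passed 2-fold upwards and 1 downwards, and 95.5% of the intervals held 0. The genes set to differ were drawn from a higher minimum than 1 CPM, so changed genes near the 1 CPM filter were not tested. Of 50 genes set 3-fold higher, 100% passed the 2-fold rule, and of 50 set 3-fold lower, 98% passed. Of the genes set 1.5-fold higher or lower, 0% passed.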

Results

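PHF12 transcript was lower in the PHF12 knockdown library of H1299 cells than in the control library, at 0.753 of the control level, and HDAC1 transcript was higher, at 1.39 times the control level. EGFR transcript stood at 0.857 of the control level and AKT1 at 1.15 times. Across gene groups, amino acid response genes controlled by ATF4, NF-kB and inflammatory genes, immediate early genes and NOTCH pathway genes were lower together in the knockdown library. Interferon-stimulated genes and replication-dependent histone genes were higher together, though reads of the histone genes are uncertain in poly(A)-selected libraries.

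The data were poly(A)-selected RNA-seq libraries from H1299, a human non-small cell lung cancer line established from a lymph node metastasis. There were 2 libraries, 1 labelled as control with no treatment, though its title ends in nc, and 1 labelled as PHF12 knockdown. PHF12 encodes a zinc finger protein of the PHD type that is a subunit of a Sin3 and HDAC corepressor complex, and the series asks how it relates to HDAC1 and to EGFR and AKT signalling. The control library held 24740581 counts and the knockdown library 26084594 counts, with at least 1 count for 22485 and 22557 genes. Protein-coding genes took 97.3% of the counts in both libraries. Fold changes below are the knockdown library over the control library. With 1 library per group the differences have no replicate check, describe these 2 libraries and not the conditions, and carry 95% intervals that cover counting error only.

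The targeted gene came first. PHF12, on chromosome 17 from 28905250 to 28951518 on the minus strand (hg38), had 947 counts in the control library and 756 in the knockdown library. The authors' TPM values were 11.4 and 8.71. The log2 ratio was −0.41 (95% counting interval −0.55 to −0.27), and 8.90% of the 14559 genes measured had a larger absolute fold change. HDAC1, a class I histone deacetylase encoded on chromosome 1 from 32292083 to 32333628, had 2936 and 4330 counts, TPM values of 132 and 187, and a log2 ratio of 0.48 (0.41 to 0.54). EGFR, the epidermal growth factor receptor gene on chromosome 7 from 55019017 to 55211628, had 3745 and 3403 counts, TPM values of 36.9 and 32.1, and a log2 ratio of −0.22 (−0.29 to −0.16).

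AKT1 and AKT2 encode serine/threonine kinases downstream of PI3K. AKT1, on chromosome 14 from 104769349 to 104795748, had 6615 and 8094 counts and a log2 ratio of 0.21 (0.16 to 0.25). AKT2 had 8559 and 8548 counts and a log2 ratio of −0.09 (−0.13 to −0.04). AKT1 overlaps a measured gene on the other strand (LOC102723342), so part of its counts could not be assigned with certainty. The reference genes give a scale for these values: ACTB had a log2 ratio of 0.22 (0.20 to 0.24), about as far from 0 as EGFR, GAPDH one of −0.10 (−0.11 to −0.09), and HPRT1, from the list of reference genes, one of −0.38 (−0.48 to −0.29), nearly as far from 0 as PHF12.

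**Figure D1:**
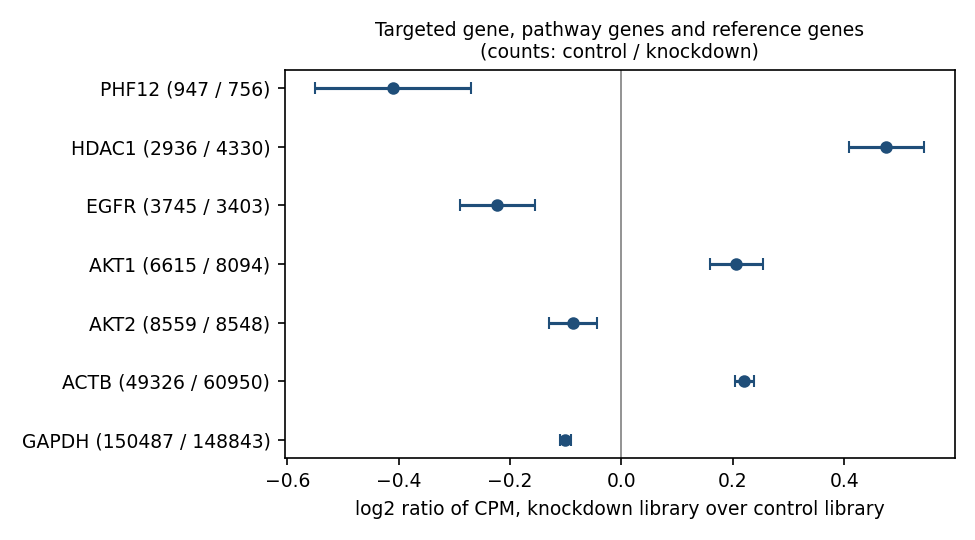
Log2 ratio of normalised counts (CPM) in the knockdown library over the control library (horizontal axis) for PHF12, the pathway genes and the reference genes ACTB and GAPDH, with the raw counts of the control and knockdown libraries beside each name. Points are ratios of 1 library per group and bars are 95% counting intervals; HDAC1 lies furthest to the right at 0.48 and PHF12 furthest to the left at −0.41.

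Across the transcriptome 14559 genes had a mean of at least 1 CPM (counts per 1000000 counts), and 97.3% of them lay within 1.5-fold. At least 2-fold higher in the knockdown library were 17 genes, of which 10 were protein-coding, 4 long non-coding RNAs (FTX, LINC01783, LOC102724351 and LOC105369301) and 3 transcribed pseudogenes (LOC441666, SSPOP and ZNF702P). At least 2-fold lower were also 17 genes, of which 14 were protein-coding, 1 a long non-coding RNA (RTCA-AS1) and 2 ribosomal RNA genes (RNA28SN3 and RNA45SN3). These non-coding genes were named after their values were seen, and the ribosomal RNA genes have near-identical copies. RNA28SN3 lies wholly within RNA45SN3 on the same strand of chromosome 21, so they are not separate loci. In simulated libraries with no difference but counting noise, 0 genes passed the rule upwards and 1 downwards.

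Among protein-coding genes with a mean of at least 5 CPM, the lowest fold was that of BIRC3, which encodes the apoptosis inhibitor cIAP and is a target of NF-kB. It lies on chromosome 11 from 102317373 to 102339403 and had 3018 counts in the control and 1016 in the knockdown library, a fold of 0.317 (0.295 to 0.341). GAGE2A, a cancer-testis antigen of a family of near-identical copies on the X chromosome, stood at 0.321 (0.304 to 0.339), with uncertain assignment of its reads. EMC10, a subunit of the endoplasmic reticulum membrane protein complex, stood at 0.388 (0.357 to 0.421), and ERFE, the hormone erythroferrone, at 0.387 (0.307 to 0.485). The Golgi GTPase gene ARF1 stood at 0.496 (0.475 to 0.517), the proteasome chaperone gene PSMD10 at 0.493 (0.444 to 0.547) and the stress-induced secreted factor GDF15 at 0.492 (0.436 to 0.555). The other lower genes were ELFN1, PABPC1 (the cytoplasmic poly(A)-binding protein), ULBP1 (a ligand of the NKG2D receptor), VCL (vinculin of focal adhesions) and the splicing regulator HNRNPM, with folds from 0.504 for ELFN1 to 0.528 for HNRNPM. PABPC1 was abundant, with 69496 and 37988 counts, and has processed pseudogenes, and VCL overlaps AP3M1 on the other strand.

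The highest fold among these protein-coding genes was that of OGFR, the opioid growth factor receptor, at 2.26 (2.07 to 2.46) with 751 and 1798 counts. TPM4, an actin-binding tropomyosin on chromosome 19 from 16067507 to 16103005, stood at 2.20 (2.14 to 2.28) with 5411 and 12649 counts. STX12, an endosomal syntaxin, stood at 2.15 (1.91 to 2.42), HABP4 at 2.11 (1.97 to 2.27) and the dynein adaptor gene BICD2 at 2.10 (1.96 to 2.25). Other higher genes were the zinc finger genes ZNF548, ZSCAN29, ZNF91 and ZNF721, the lysine methyltransferase gene SETD7 and the kinase gene CDK14, with folds from 1.98 for CDK14 to 2.20 for ZNF548. ZNF721 shares part of its span with the pseudogene ABCA11P on the same strand.

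Of the 12 lower genes, 7 (BIRC3, EMC10, ARF1, PSMD10, PABPC1, VCL and HNRNPM) held ACATCGA or CATCGAA in the annotated 3′ UTR. These are 7-base words that were over-represented among lower genes and that 2.68% of measured protein-coding genes with an annotated 3′ UTR held. Of the higher genes named, 5 (TPM4, HABP4, BICD2, SETD7 and CDK14) held TCGGAGA or ATCGGAG, the words over-represented among higher genes, which 3.08% of the same genes held. The words were found in genes at least 1.5-fold lower or higher, which include the genes named here, so these numbers are no separate test. EMC10, AKT1 and PHF12 also held a word of the higher genes, and HDAC1 and EGFR held none of these words.

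**Figure D2:**
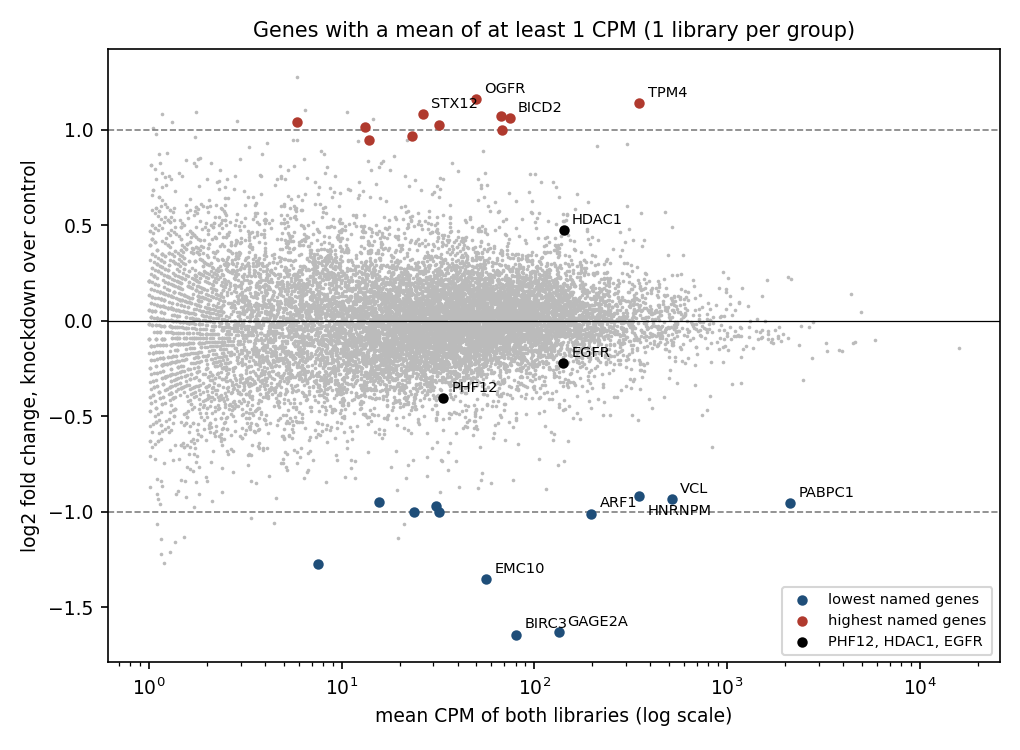
Log2 fold change of the knockdown over the control library (vertical axis) against mean CPM of both libraries (horizontal axis, log scale) for the 14559 genes measured, 1 library per group. Blue and red points are the lowest and highest genes named in the text, black points are PHF12, HDAC1 and EGFR, and dashed lines mark 2-fold; BIRC3 lies lowest, and most genes lie within 1.5-fold.

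Gene lists fixed in advance were described by their median log2 fold change and its percentile among 10000 random lists matched on size and expression. Of 45 lists with at least 5 measured genes, 13 lay below and 5 above the central 95% of random medians, where chance alone would put 2.25 lists outside. Random lists of unrelated genes ignore that genes of a pathway vary together between any cultures.

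Lists of Sin3 and HDAC genes, ERBB receptors and signalling components lay within the random range. The Sin3 and HDAC complex list had a median of 0.06 over 26 genes (93.8th percentile), with HDAC1 at 0.47, EMSY at 0.33 (0.18 to 0.49) and BRMS1L at −0.28 (−0.56 to −0.03). Histone deacetylases and sirtuins had a median of −0.09 over 18 genes (5.0th percentile), with HDAC4 at −0.59 (−0.94 to −0.33), which held a word of the lower genes, opposite in direction to HDAC1. ERBB receptors and ligands had a median of −0.14 over 11 genes (3.95th percentile), led by the EGFR feedback inhibitor ERRFI1 at −0.49 (−0.52 to −0.47), the receptor inhibitor LRIG1 at −0.42 (−0.67 to −0.21) and the ligand TGFA at 0.32 (0.12 to 0.53). With a minimum of 5 CPM this list lay below the random range, at the 1.08th percentile, and likewise with a GC and length trend removed, at the 1.87th, while with the deposited TPM and without the expression filter its median was −0.03, at the 28.6th and 32.3rd percentiles. EGFR adaptors and the RAS-MAPK cascade had a median of 0.04 over 24 genes (85.3rd percentile), with NRAS at 0.45 (0.38 to 0.52) and HRAS at −0.32 (−0.46 to −0.19). PI3K, AKT and mTOR components had a median of 0.02 over 31 genes (67.3rd percentile), with the mTOR complex gene MLST8 at −0.50 (−0.62 to −0.39) and the transcription factor FOXO1 at −0.34 (−0.85 to 0.06) on 93 and 75 counts.

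The lists of ERK output genes, FOXO targets, immediate early genes and other receptor tyrosine kinases lay lower in the knockdown library. ERK output genes had a median of −0.11 (0.40th percentile), with 13 of 17 below 0, among them PHLDA1 at −0.47 (−0.49 to −0.44), IER3 at −0.39 (−0.49 to −0.30), the cyclin gene CCND1 at −0.33 (−0.36 to −0.29) and MYC at −0.30 (−0.35 to −0.26). FOXO targets, which AKT activity is known to repress, had a median of −0.14 (1.84th percentile), with 11 of 16 below 0. Their leading members were GADD45A at −0.88 (−0.96 to −0.81), PIK3IP1 at −0.53 (−0.95 to −0.23) and CITED2 at −0.52 (−0.62 to −0.43). Immediate early genes had a median of −0.32, below all 10000 random lists (percentile 0), with 13 of 16 below 0. NR4A2 stood at −0.68 (−1.10 to −0.39), JUNB at −0.55 (−0.63 to −0.48) and ZFP36 at −0.54 (−0.65 to −0.45), while FOSB, with 64 and 135 counts, was higher at 0.87 (0.55 to 1.44). Receptor tyrosine kinases other than the ERBB family had a median of −0.20 (0.050th percentile), with 15 of 17 below 0, including MERTK at −0.49 (−0.61 to −0.38) and DDR2 at −0.52 (−1.13 to −0.12). Of the genes in this list, 4 held a word of the lower genes and 3 a word of the higher genes, with EPHB4 and FLT4 counted in both. Without genes holding a word, the median over the remaining 12 was −0.21 (0.10th percentile).

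The lowest list was that of ATF4 and the amino acid response, with a median of −0.49 and all 24 genes below 0 (percentile 0). STC2 stood at −0.85 (−0.96 to −0.75), the glutathione-degrading enzyme CHAC1 at −0.83 (−0.96 to −0.73) and the cysteine-synthesis enzyme CTH at −0.82 (−1.12 to −0.60). The mTOR inhibitor DDIT4 stood at −0.75 (−0.83 to −0.68), although it held a word of the higher genes. Of its genes, 6 were at least 1.5-fold lower. NF-kB and inflammatory genes had a median of −0.39 (percentile 0), with 11 of 13 below 0. After BIRC3, this list was led by CXCL3 at 0.98 (0.60 to 2.49) on only 14 and 42 counts, the cytokine LIF at −0.62 (−0.73 to −0.52) and the chemokine CXCL2 at −0.58 (−0.66 to −0.51). NOTCH pathway genes had a median of −0.23 (0.12th percentile), with 14 of 15 below 0, including the transcriptional repressor HES1 at −0.83 (−1.23 to −0.56), HEY2 at −0.63 (−1.80 to −0.11) and the ligand DLL1 at −0.56 (−1.14 to −0.17).

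Unfolded protein response genes had a median of 0.09 (98.2nd percentile) with members on both sides of 0, among them XBP1 at −0.44 (−0.55 to −0.34), HYOU1, which held a word of the lower genes, at −0.37 (−0.45 to −0.29), HERPUD1 at −0.28 (−0.39 to −0.17) and EDEM1 at 0.26 (0.12 to 0.41), and a mean of 0.03. Without the expression filter this list was at the 97.4th percentile, within the range of random lists. Heat shock genes had a median of 0.10 (98.4th percentile), with 11 of 13 above 0, including the chaperones HSPA1A at 0.30 (0.18 to 0.43) and HSPA8 at 0.23 (0.21 to 0.24). Autophagy and lysosome genes had a median of 0.08 (98.6th percentile), with 17 of 25 above 0, including BECN1 at 0.43 (0.32 to 0.56) and ATG14 at 0.41 (0.25 to 0.58), and lay just inside the random range with the GC and length trend removed. NRF2 targets had a median of −0.07 (5.10th percentile), with the malic enzyme ME1 at 0.51 (0.37 to 0.67) and the cystine transporter SLC7A11 at −0.50 (−0.63 to −0.39). Hypoxia genes had a median of −0.03 (29.7th percentile), led by STC2 and NDRG1, the latter at −0.48 (−1.44 to 0.08) on 39 and 26 counts.

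Among proliferation genes, the G1/S and DNA replication list had a median of −0.15 (percentile 0), with 32 of 34 genes below 0. TYMS, the thymidylate synthase, stood at −0.73 (−0.80 to −0.67), E2F2 at −0.50 (−0.75 to −0.30) and the replication licensing factor CDT1 at −0.45 (−0.52 to −0.38). G2/M genes had a median of −0.02 (16.9th percentile), with the mitotic kinase PLK1 at −0.59 (−0.67 to −0.52) and its target CDC25C at −0.26 (−0.42 to −0.11). D-type cyclins and CDK inhibitors had a median of −0.05 (13.6th percentile), with CDKN1C at −0.78 (−1.24 to −0.49) and CCND2 at −0.56 (−1.22 to −0.15), and lay at the 2.47th percentile, just below the random range, with the GC and length trend removed. Replication-dependent histone genes had a median of 0.20 (99.8th percentile), with 12 of 14 above 0, led by H2BC5 at 0.86 (0.69 to 1.08), H2BC8 at 0.65 (0.29 to 1.21) and H3C8 at 0.59 (0.30 to 1.0). These histone genes have close paralogs and mostly lack poly(A) tails, so their reads are uncertain in poly(A)-selected libraries. Of 22 listed, 14 passed the expression filter, and no median was available for them with the GC and length trend removed. Homologous recombination and DNA repair genes had a median of −0.10 (0.93rd percentile), with 22 of 27 below 0, including XRCC3 at −0.34 (−0.42 to −0.26) and EXO1 at −0.28 (−0.47 to −0.11).

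Pro-apoptotic BCL2 family genes had a median of −0.18 (0.88th percentile), with BIK at −0.63 (−1.33 to −0.22) and PMAIP1 at −0.41 (−0.57 to −0.26). Their median was inside the random range with a minimum of 5 CPM (6.59th percentile) and with the GC and length trend removed (28.4th percentile). Anti-apoptotic genes had a median of 0.09 (92.6th percentile) and, with BIRC3 far below the others, a mean of −0.12. BCL2L1 stood at 0.47 (0.41 to 0.53) and MCL1 at −0.46 (−0.50 to −0.42).

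Interferon-stimulated genes had the highest median, at 0.23, above all 10000 random lists (percentile 100), with 28 of 29 above 0. Whether the control cells received an oligonucleotide is not given. An effect of PHF12, one of transfection and a difference between single cultures therefore cannot be told apart for this list. MX1, an antiviral GTPase, stood at 0.89 (0.64 to 1.26), IFI27 at 0.79 (0.40 to 1.56), OAS2 at 0.68 (0.44 to 1.0) and IFIT1 at 0.57 (0.47 to 0.68). MHC class I genes had a median of −0.03 (27.4th percentile), with the immunoproteasome gene PSMB10 at −0.40 (−0.61 to −0.21) and PSMB9 at −0.30 (−0.57 to −0.06). Cancer-testis antigens had a median of 0.11 (96.9th percentile), with CTCFL at 0.74 (0.43 to 1.23) opposite to GAGE2A. This list lay above the random range among protein-coding genes alone (97.8th) and with the GC and length trend removed (99.2nd), while without the expression filter its median was 0.06 (88.7th).

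Lists of cell identity and adhesion lay within the random range. Epithelial genes had a median of −0.14 (3.58th percentile), with CLDN3 at −0.51 (−1.02 to −0.15) and KRT7 at −0.44 (−1.05 to −0.01), and mesenchymal genes a median of −0.01 (48.2nd percentile), with TWIST1 at −0.53 (−0.76 to −0.33) and TGFBI at 0.35 (0.22 to 0.49). Without the expression filter both lay below the range, at the 0.64th and 1.92nd percentiles. Matrix proteases and the plasminogen system had a median of 0.04 (78.5th percentile), while the abundant urokinase transcript PLAU, with 25362 and 16992 counts, stood at −0.66 (−0.69 to −0.63) and MMP15 at 0.55 (0.10 to 1.26). Integrins had a median of 0.08 (93.8th percentile), with ITGB4 at −0.32 (−0.46 to −0.19) and ITGA1 at 0.24 (−0.0033 to 0.51). TGF-beta and BMP targets had a median of 0.01 (57.8th percentile), with ID3 at −0.82 (−1.11 to −0.61) and SMAD6 at −0.62 (−1.46 to −0.16). YAP/TEAD targets had a median of −0.04 (18.7th percentile), with TGFB2 at −0.49 (−0.86 to −0.20) and F3 at 0.46 (0.07 to 0.99), and WNT targets a median of −0.06 (39.8th percentile), with TCF7 at −0.33 (−0.55 to −0.13) and DKK1 at −0.20 (−0.49 to 0.07). Neuronal and neuroendocrine genes had a median of −0.01 (48.2nd percentile), with SYT1 at 0.37 (0.16 to 0.60) and STMN3 at −0.35 (−0.45 to −0.26).

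Medians of growth and metabolism lists lay close to 0. Cytosolic ribosomal protein genes had a median of −0.05 (0.040th percentile), with 66 of 77 below 0, and the leading members RPS9 (which held words of both kinds) and RPLP1 both at −0.15; reads of these genes can be shared with pseudogenes. Nucleolar ribosome biogenesis genes had a median of −0.08 (0.18th percentile), with 21 of 28 below 0, while NOLC1, which held a word of the higher genes, stood at 0.92 (0.86 to 0.98) and RRP9 at −0.27 (−0.42 to −0.13). Glycolysis genes had a median of −0.04 (13.0th percentile), with ENO2 at 0.27 (0.19 to 0.36) and SLC2A3 at 0.20 (0.15 to 0.25), and without the expression filter lay at the 1.91st percentile. Cholesterol biosynthesis genes had a median of −0.01 (41.2nd percentile), with FDPS at 0.35 (0.31 to 0.38) and INSIG1 at 0.29 (0.25 to 0.34). Fatty acid synthesis genes had a median of −0.01 (40.5th percentile), with FASN at −0.31 (−0.33 to −0.30) and ELOVL7 at −0.23 (−0.39 to −0.07). Nuclear-encoded oxidative phosphorylation genes had a median of −0.02 (9.21st percentile), with the complex I gene NDUFS8 at −0.53 (−0.63 to −0.44).

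Markers of other cell types were mostly below the expression minimum. Only 2 of 17 leukocyte markers (ITGAM and CD68), 3 of 12 fibroblast markers (ACTA2, PDGFRB and COL1A1) and 2 of 16 lung epithelium markers (AGER and ABCA3) passed it, too few for a percentile. Their log2 fold changes were −0.55 (−1.0 to −0.22) for ITGAM, 0.29 (0.23 to 0.35) for CD68, 0.39 (0.07 to 0.79) for ACTA2, −0.22 (−1.08 to 0.44) for PDGFRB, 0.20 (−0.31 to 0.81) for COL1A1, −0.50 (−1.14 to −0.08) for AGER and 0.11 (0.03 to 0.20) for ABCA3. Endothelial markers had a median of 0.07 over 7 genes (75.1st percentile), with KDR at −0.46 (−1.05 to −0.04) and EGFL7 at −0.36 (−0.51 to −0.23). As for RNA quality, the list of non-polyadenylated and nuclear-retained RNAs had a median of 0.07 (87.3rd percentile). Its leading members were SNHG1 at −0.48 (−0.58 to −0.40), NEAT1 at 0.39 (0.35 to 0.44) and RN7SL2 at 0.35 (0.23 to 0.49). Whether SNHG1 has these traits was not tested. Ribosomal RNA, with mitochondrial ribosomal RNA included, took 0.516% of counts in the control and 0.462% in the knockdown library. Reference genes had a median of −0.08 (3.53rd percentile), with HPRT1 at −0.38 (−0.48 to −0.29) furthest from 0. The mitochondrially encoded mRNAs were not analysed here.

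**Figure D3:**
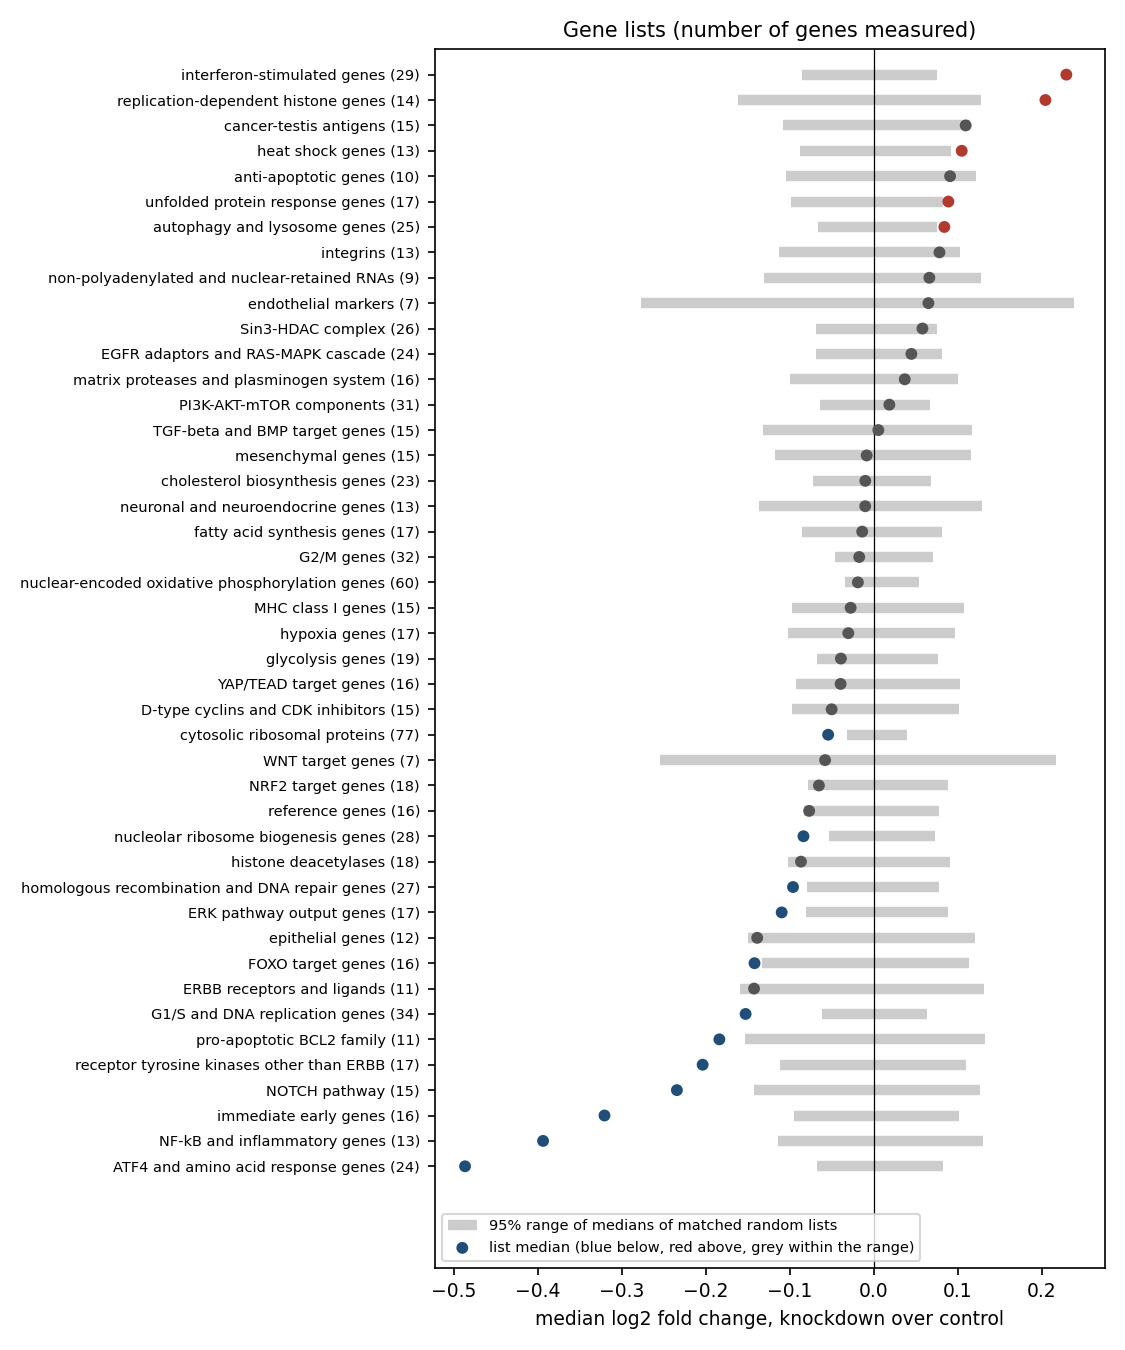
Median log2 fold change of the knockdown over the control library (horizontal axis) for the gene lists reported here with at least 5 measured genes, whose numbers stand in brackets. Points are list medians and grey bars the 95% range of medians of 10000 matched random lists; blue points lie below their bar, with ATF4 targets lowest at −0.49, and red points above, with interferon-stimulated genes highest at 0.23.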

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

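The settings with the GC and length trend removed and without genes holding an over-represented word were chosen only after the results were seen. The counts of genes at least 2-fold higher and lower, 17 and 17, moved with the pseudocount: 0.1 gave 37 and 37 genes, and 1 gave 10 and 7, because the pseudocount sets how far genes with few counts are pulled towards 0. The deposited TPM values gave 127 and 110 genes, which held 22 of the 34. There the minimum of 1 and the pseudocount of 0.5 were applied to TPM in place of CPM, and 15214 genes passed against 14559. How much of the change this explains was not tested. A fold of at least 1.5 gave 193 and 205. A minimum of 5 CPM gave 12 and 8 and protein-coding genes alone gave 10 and 14, both by construction, from fewer genes. Removing the GC and length trend, for protein-coding genes alone, gave 9 and 10. Scaling by total counts gave 18 and 16, DESeq2 size factors 18 and 15, no filter 18 and 20, the thinned knockdown library 19 and 17, and leaving out genes with a word 13 and 12. None of the study genes and genes named by size and no list outside the random range changed its sign, while some medians near 0 did, such as that of MHC class I genes, at 0.01 with the GC and length trend removed. Under the alternatives, every value of PHF12, HDAC1, EGFR and AKT1 and every median of the Sin3 and HDAC, ERBB and PI3K lists stayed within its counting interval. For single genes and for lists this was partly set in advance. The median of a list of protein-coding genes cannot change when only protein-coding genes are kept. Nor can it change under a filter that leaves the list's measured genes the same. Scaling by total counts or by DESeq2 shifts all log2 ratios alike, by 0.008 and 0.019. The filters, the thinned library and the leaving out of genes with a word were not run for single genes. Of the values of the other study genes and genes named by size 166 stayed within and 8 did not (those of ACTB, GAPDH and PABPC1), and of the other list medians 406 and 10. Over the settings run for them, log2 fold changes ranged from −0.42 to −0.37 for PHF12, 0.47 to 0.50 for HDAC1, −0.27 to −0.20 for EGFR and 0.21 to 0.25 for AKT1. The log2 fold change falls with GC content, from a median of 0.02 in the 1237 genes lowest in GC (37.1%) to −0.11 in the 1237 highest (64.6%). Depth limits genes with few counts, such as CXCL3 with 14 and 42, whose interval runs from 0.60 to 2.49.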

Other observations

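The tests on the zinc finger family, the search for words and the GC and length correction were chosen only after the fold changes were seen.

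Genes whose symbol is ZNF and a number, with or without a final letter, most of which encode zinc finger transcription factors, were higher together in the knockdown library. Over 465 measured members the median log2 fold change was 0.08, where matched random lists lay between −0.06 and −0.02, and 290 members were above 0, while 3 members (ZNF438, ZNF773 and ZNF835) were at least 1.5-fold lower. Of the 135 protein-coding genes at least 1.5-fold higher, 28 belonged to this family (20.7%), against 3.67% of all protein-coding genes measured. Long non-coding RNAs also leaned upwards, with a median of 0.06 over 1473 genes against −0.01 for 12669 protein-coding genes.

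The zinc finger pattern could reflect base composition, since these transcripts have a median GC content of 43.1% against 48.5% for all protein-coding genes and the fold change falls with GC content. With the trend on GC content and length removed, the family's median was still 0.081, above the random range, so the trend removed was not the whole cause. A few members did not carry the family either, since 62.4% of members were above 0, where the upper end of the random range was 46.9%. Without the members at least 1.5-fold higher the median was 0.06, and without genes holding an over-represented word 0.08. A difference between the 2 cultures unrelated to PHF12 stays open.

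The ATF4 and amino acid response list was lower in all its 24 genes. Its median was −0.46 after the GC and length trend was removed, still below the random range, so the trend removed was not the whole cause. A difference in medium, density or time of harvest between 2 single cultures could give the same pattern. With 1 library per group, an effect of the PHF12 knockdown and a difference between single cultures cannot be told apart for this list.

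Genes at least 1.5-fold apart between the libraries shared short words in their 3′ UTRs. Among 169 protein-coding genes at least 1.5-fold lower with an annotated 3′ UTR, 18 held ACATCGA where 2.37 were expected (z = 8.60), and 18 held CATCGAA. The highest z of any word in 1000 matched random gene sets was 6.13. Among 126 genes at least 1.5-fold higher, 17 held TCGGAGA where 2.98 were expected (z = 7.13, against at most 5.74 in random sets), and 13 held ATCGGAG. With the expected numbers also matched on GC content of the 3′ UTR, the z values of ACATCGA and TCGGAGA were 8.36 and 7.0. Either lower word was present in 24 of the lower genes (14.2%) and in 2.68% of all genes with a 3′ UTR, and either higher word in 20 of the higher genes (15.9%) and in 3.08% of all.

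A candidate explanation is that small RNAs with seeds complementary to these words acted through 3′ UTRs, one more active in the knockdown cells and another more active in the control cells. The test could have failed outside the genes that showed the pattern. Among 12020 genes within 1.5-fold, however, the 179 with ACATCGA had a median of −0.095 (random lists −0.02 to 0.04). The 238 with TCGGAGA had one of 0.059 (random lists −0.02 to 0.03). These random lists were matched on expression and 3′ UTR length but not on GC content, so base composition was not tested here. PHF12 itself holds the joined word ACATCGAA in 3 of its 9 annotated protein-coding transcripts, in the coding sequence of exon 6, on chromosome 17 from 28919152 to 28919159 on the minus strand (GRCh38), as a target site of a PHF12 oligonucleotide would. Chance could also give this, since 3.44% of 1830 genes with transcripts of similar length hold the joined word on the same strand and 6.72% on either. For ACATCGA these shares are 16.6% and 25.2%. Only the longest transcript of each other gene was searched, against all 9 of PHF12, so these shares may understate chance. PHF12 also holds TCGGAGA, the word of the higher genes, in 2 of the 9 transcripts, and the joined word ATCGGAGA in 0. A PHF12 transcript with a 7-base word is thus weak evidence. The control's title ends in nc while its treatment label gives none, and the oligonucleotides used are not given in the sources used here, so part of the difference between these libraries may be unrelated to PHF12, including at BIRC3 and TPM4, while most genes past 1.5-fold hold none of these words and are not addressed by this test.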
